A study of Homo sapiens with 4 samples.

How the data were processed

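Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against MDM2 in H1299 cells, an established human lung carcinoma line that lacks p53. MDM2 is an E3 ubiquitin ligase best known for marking p53 for degradation. Of the 4 samples, 2 were MDM2 ChIP libraries and 2 were the input DNA belonging to them. One ChIP library came from cells overexpressing an Mdm2 variant named Delta AD in the labels, and the other from cells in which Mdm2 was knocked down with a short hairpin RNA (shMdm2). Each group held 1 library. Per the labels' protocols, cells were crosslinked for 5 minutes with 1% formaldehyde, and chromatin was sonicated to below 500 nucleotides. The protocols also name empty vector and scrambled hairpin controls, which were not analysed here. No read data or input coverage were used here.

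The authors' deposited files were 2 peak lists in BED format, 1 for each ChIP library. Reads were aligned with Bowtie and peaks were called with MACS 1.0.1 on the hg19 build, per the submitters' processing notes, and MACS was run in Galaxy, per the file headers. The settings of the calls are not given in the sources used here. Each deposited row holds a position, a name and the peak score that the authors' caller gave. MACS usually writes a negative log10 of the p-value, scaled, in this column, but the files do not say so, and the values were treated as scores. The lowest deposited score was 33.02 in the Delta AD list and 50 in the shMdm2 list, so the lists end at different scores. A score also depends on library size and on the input, so equal scores in the 2 libraries need not mean equal enrichment. The depth of each library is unknown, and no limit of detection can be given. In the Delta AD list 673 of 6478 peaks shared 1 score, 38.45.

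Peak starts were converted to 1-based positions. Peaks were called shared where they overlapped by at least 1 bp. The number shared was set beside 1000 random placements of the Delta AD peaks on their own sequences, between the first and last peak of either list, with widths kept. Peaks per Mb used the end of the last peak on a chromosome as its length. Regional density was counted in 5 Mb bins on chromosomes 1 to 22 and X. Shares of peaks carry exact Clopper-Pearson 95% intervals, and ratios of peak numbers carry exact conditional binomial 95% intervals. These intervals cover counting error only, treat peaks as independent, and say nothing about variation between cultures. With 1 library per group there was no test between conditions, and no p-value between the groups is given. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

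The overlap count and the bin comparison were checked on simulated lists of 6356 and 162 peaks. With 20 shared peaks planted, all of 20 simulated pairs returned the planted peaks with at most 5 more, and all of 20 exceeded every random placement. With regional density differing 4-fold in both lists, the bin comparison passed its limit in 20 of 20 simulations, and in 1 of 20 when only 1 list had the blocks. These simulations used fewer random placements and shifts than the data, and more planted peaks than the lists shared. Lists with separate blocks in each were not simulated, so the check does not cover that case.

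The main settings, the other settings to be tried and the rule for named items were fixed before the data were examined. Promoter shares, annotation classes, fixed gene lists and sequence motifs had also been planned. They were not evaluated, because no hg19 annotation or sequence was used here, and the gene table at hand was of GRCh38. That table served only for the number of protein-coding genes per chromosome and for the chromosome of MDM2. Under the rule for this case, the 10 highest-scoring peaks of each list and every shared peak are named by hg19 coordinates. The other settings were a common score minimum, removal of chromosome Y and unplaced contigs, merging of peaks closer than 1 kb, other definitions of overlap, and random placement within 1 Mb.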

Results

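MDM2 occupancy was mapped in 2 ChIP-seq libraries from H1299 cells, 1 with overexpressed Mdm2 Delta AD and 1 with Mdm2 knocked down, in order to locate chromatin binding sites of MDM2 across the genome. The data were the authors' peak lists. There were no replicates, so every difference described below is between 2 libraries and has no replicate check. The sequencing depth behind the lists is unknown.

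The first comparison asked how many sites were called with the Delta AD variant overexpressed and with Mdm2 knocked down. Amount and form of the protein differed together between these libraries. The Delta AD list held 6478 peaks covering 1163 kb, and the shMdm2 list held 187 peaks covering 102 kb, a ratio of 34.6 (95% interval 30.0 to 40.3). The lists end at different scores, so this ratio sets unlike score minimums side by side. Most of the difference lay at scores where the shMdm2 list ends and holds no peak. How many shMdm2 peaks would lie there is unknown. In the Delta AD list 6067 peaks, or 93.7%, scored below 50, the lowest score of the shMdm2 list. At or above a score of 50 there were 411 Delta AD and 187 shMdm2 peaks, a ratio of 2.20 (1.84 to 2.63). At or above 55 the ratio was 1.53 (1.19 to 1.99, from 158 and 103 peaks). At or above 60 it was 1.11 (0.777 to 1.60, from 68 and 61 peaks), the lowest of the score minimums tried. It was 1.80 (0.924 to 3.64) at 70, 1.45 (0.634 to 3.47) at 80 and 2.25 (0.628 to 10.0, from 9 and 4 peaks) at 100, so from 60 upwards the intervals included equality.

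**Figure D1:**
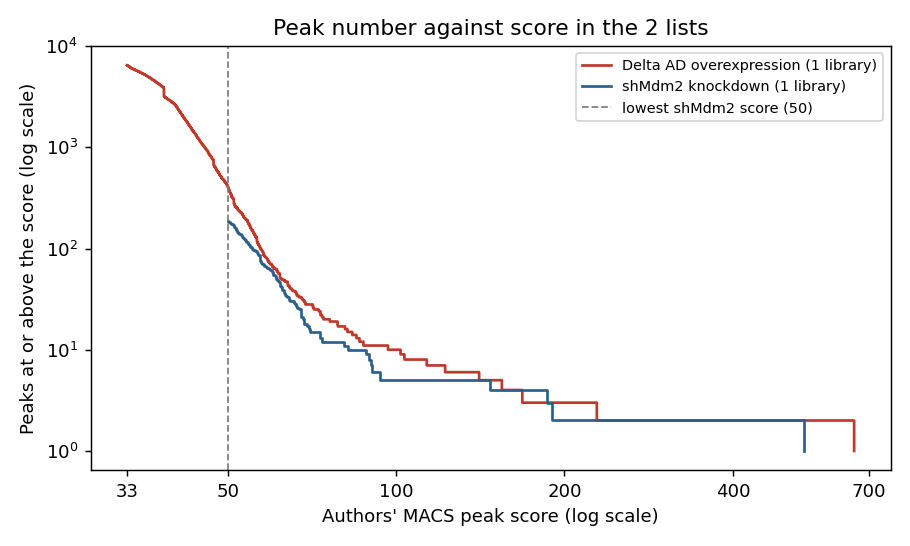
Number of peaks at or above each authors' MACS score in the Delta AD library and the shMdm2 library, with both axes on log scales and 1 library per line. The Delta AD line starts at a score of 33.02 with 6478 peaks and has come down to 411 at the dashed line, where the shMdm2 line starts with 187.

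Typical peaks were narrow in both lists. The median width was 172 bp (quartiles 156 and 183) for Delta AD and 168 bp (quartiles 154.5 and 200.5) for shMdm2. Median scores were 38.45 and 55.95, which were set in part by the different lowest scores. The lists differed in the share of wide peaks. Peaks over 1 kb numbered 14 of 187 in the shMdm2 list (7.49%, 4.15 to 12.2) and held 67.3% of its covered length. In the Delta AD list they numbered 9 of 6478 (0.139%, 0.0635 to 0.264) and held 2.09%, and among its peaks at or above a score of 50 they numbered 6 of 411 (1.46%, 0.538 to 3.15) and held 20.2%. Of the 14 wide shMdm2 peaks, 4 lay on unplaced contigs and 10 on chromosomes 1, 2, 10, 16, 19 and X, where they bordered the centromeres by the known layout of these chromosomes. The 9 wide Delta AD peaks lay in places of the same kind, 3 on unplaced contigs and 6 beside the centromeres of chromosomes 2, 4, 10 and 16. The widest shMdm2 peaks were 21.4 kb on chromosome 16, 15.6 kb on chromosome X and 10.2 kb on chromosome 2. Unplaced contigs held 11 shMdm2 peaks (5.88%, 2.97 to 10.3) and 52 Delta AD peaks (0.803%, 0.600 to 1.05), of which 6 scored 50 or more (1.46% of 411, 0.538 to 3.15).

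The second comparison asked which sites were called in both libraries. Only 9 peaks of each list overlapped, which was 4.81% of the shMdm2 peaks (2.22 to 8.94) and 0.139% of the Delta AD peaks (0.0635 to 0.264). Random placement of the Delta AD peaks gave 0.758 overlapping peaks on average and at most 4 in 1000 placements. Without chromosome Y and the unplaced contigs, 6 peaks overlapped and random placement gave 0.243 on average and at most 2. This version was added after the data were examined. Both placements were uniform along each sequence. They cannot separate overlap of binding sites from overlap at repeated sequence, such as beside centromeres. Of the 411 Delta AD peaks at or above 50, 7 overlapped an shMdm2 peak (1.70%, 0.687 to 3.48), and of the 6067 below it 2 did (0.0330%, 0.00399 to 0.119).

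A site in both lists was called with Delta AD overexpressed and with Mdm2 knocked down. Its listing alone therefore does not show that MDM2 was bound there. The highest peak was the same site in both libraries. It spanned chr11:118306644-118307239 in the Delta AD list with a score of 659.1 and chr11:118306681-118307230 in the shMdm2 list with a score of 535.32. The second highest was also the same, at 64309 to 65731 of the unplaced contig chrUn_gl000214 with a score of 228.51 for Delta AD and at 64318 to 65409 with 190.13 for shMdm2. A site at chrX:70288182-70288581 ranked 4 in the Delta AD list (score 154.59) and 75 in the shMdm2 list (57.09, at 70288407 to 70288570). On chromosome 16, the 11067 bp Delta AD peak at 46385794 to 46396860 scored 86.01 and lay almost wholly within the 21367 bp shMdm2 peak at 46385795 to 46407161, which scored 186.06. The other 5 shared sites scored between 33.39 and 63.3 in the Delta AD list and between 51.58 and 88.2 in the shMdm2 list. They were at chr21:9825766-9826382, chrY:58994884-58994975, chr16:35248813-35249098, chr7:75274324-75274475 and 113149 to 113962 of chrUn_gl000220, a contig known to carry ribosomal RNA gene sequence.

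Of the 10 highest Delta AD peaks, 3 overlapped an shMdm2 peak, the sites on chromosome 11, chrUn_gl000214 and chromosome X. The other 7 had no shMdm2 peak over them. The highest of these was chr12:125396501-125397102, 602 bp wide with a score of 168.14, and the nearest shMdm2 peak was 44213.5 kb away. Chromosome Y held 3 of them, at 58827292 to 58827409 (score 140.76), 58822201 to 58822608 (113.46) and 58834632 to 58834946 (96.73), between 160 and 172 kb from an shMdm2 peak. On chrUn_gl000220 the peak at 157073 to 157880 scored 122.38 and had an shMdm2 peak 5.95 kb away. The peak at chr21:9826781-9827683 scored 101.86 and started 0.411 kb after an shMdm2 peak. The peak at chr12:69233040-69233636 scored 103.5, with the nearest shMdm2 peak 10277.0 kb away.

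The chromosome 12 peak with a score of 103.5 did not stand alone. In 30.7 kb, the Delta AD list held 4 peaks, at 69202982 to 69203114 (score 34.17), 69207321 to 69207424 (47.81), 69222459 to 69222726 (87.44) and 69233040 to 69233636 (103.5). The upper 2 ranked 11 and 8 among all Delta AD peaks. The shMdm2 list had no peak there or within 500 kb on either side, with 4 peaks on the whole of chromosome 12. This group was described after its values were seen. MDM2 itself lies on chromosome 12, and whether these peaks lie over the gene was not tested. Reads of the introduced Mdm2 sequence may be one source of them, as set out under Other observations.

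**Figure D2:**
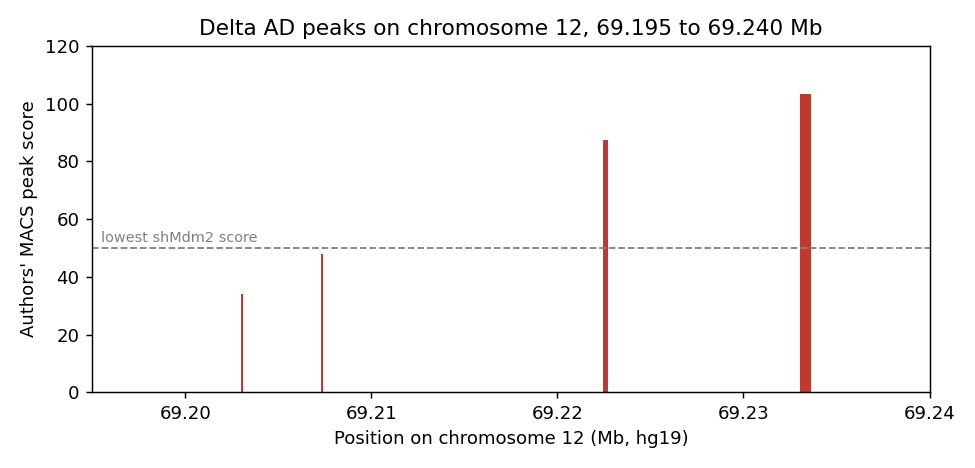
The 4 Delta AD peaks in 30.7 kb of chromosome 12, drawn to scale along the hg19 position in Mb (x axis) with bar height giving the authors' MACS score in this 1 library (y axis). The scores were 34.17, 47.81, 87.44 and 103.5 from left to right, and the shMdm2 list, whose lowest score is the dashed line, had no peak in this interval.

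Of the 10 highest shMdm2 peaks, 4 overlapped a Delta AD peak, the sites on chromosomes 11 and 16 and on both contigs. The 6 without overlap included 5 beside centromeres by the known chromosome layout. These were chr2:92315212-92325377 (score 147.39), chrX:58566363-58582005 (93.54), chr1:121483667-121485442 (90.63), chr10:42385834-42389714 (90.28) and chr10:42384888-42385821 (89.29). The remaining one was a 159 bp peak at chr2:22823999-22824157 with a score of 81.98. The chromosome 10 peaks named here lay closer together than 1 kb, so the merging setting would join them.

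The third comparison asked how the sites were spread over the chromosomes. In the full list, Delta AD peaks were most numerous on chromosome 6, with 708 peaks (10.9% of the list, 10.2 to 11.7) or 4.14 per Mb. Chromosomes 2, 5, 8 and 12 followed with 636, 570, 550 and 485 peaks. Chromosome 1, whose last peak ended at 248.2 Mb, held only 262 peaks or 1.06 per Mb, and chromosomes 13 and 22 held 44 and 21 peaks (0.406 and 0.432 per Mb). The 5 chromosomes richest in Delta AD peaks were picked by Delta AD counts, which favours the Delta AD share. Together they took 45.5% of the Delta AD peaks (44.3 to 46.7) and 32.1% of the shMdm2 peaks (25.5 to 39.3). For the 411 Delta AD peaks at or above 50 the share was 35.8% (31.1 to 40.6). Among these 411, chromosome 5 held the most, 39, followed by chromosomes 2, 7 and Y with 33, 32 and 31, and chromosome 6 held 27 (6.57%, 4.37 to 9.41). In the shMdm2 list chromosome 6 also had the most peaks, 19 (10.2%, 6.23 to 15.4). Chromosome 12 held 4 shMdm2 peaks (2.14%, 0.586 to 5.39), against 7.49% of the Delta AD peaks (6.86 to 8.15). For Delta AD peaks at or above 50 it was 6.57% (4.37 to 9.41), an interval that overlaps that of shMdm2. Chromosome 19 held 9 shMdm2 peaks (4.81%, 2.22 to 8.94), against 1.67% of the Delta AD peaks (1.37 to 2.01). At or above 50 the Delta AD share was 1.46% (0.538 to 3.15, 6 peaks), and the intervals overlapped. For chromosomes 12 and 19, overlap of the intervals does not show that the shares were equal.

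Within chromosomes the Delta AD peaks of the full list lay in dense and sparse blocks of many Mb. The boundaries given here were chosen after seeing the counts. On chromosome 8, the first 45 Mb held 29 peaks (0.644 per Mb) and the rest 521 (5.14 per Mb). On chromosome 3, the first 120 Mb held 105 peaks (0.875 per Mb) and the rest 286 (3.68 per Mb). On chromosome 2, the part from 105 to 170 Mb held 315 peaks (4.85 per Mb), against 230 before it (2.19 per Mb) and 91 after it (1.30 per Mb). The first 35 Mb of chromosome 12 held 188 peaks (5.37 per Mb) and the rest 297 (3.03 per Mb). The shMdm2 peaks in the same parts numbered 0 and 13 on chromosome 8, 2 and 5 on chromosome 3, 8, 5 and 1 on chromosome 2, and 1 and 3 on chromosome 12. Over 614 bins of 5 Mb, the median was 8 Delta AD peaks and the highest 44, at 160 to 165 Mb of chromosome 2. The variance of the bin counts was 7.26 times their mean, where independent random placement gives equality. Bins that can hold no peaks were not removed, which raises this ratio, and 32 bins had no Delta AD peak.

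**Figure D3:**
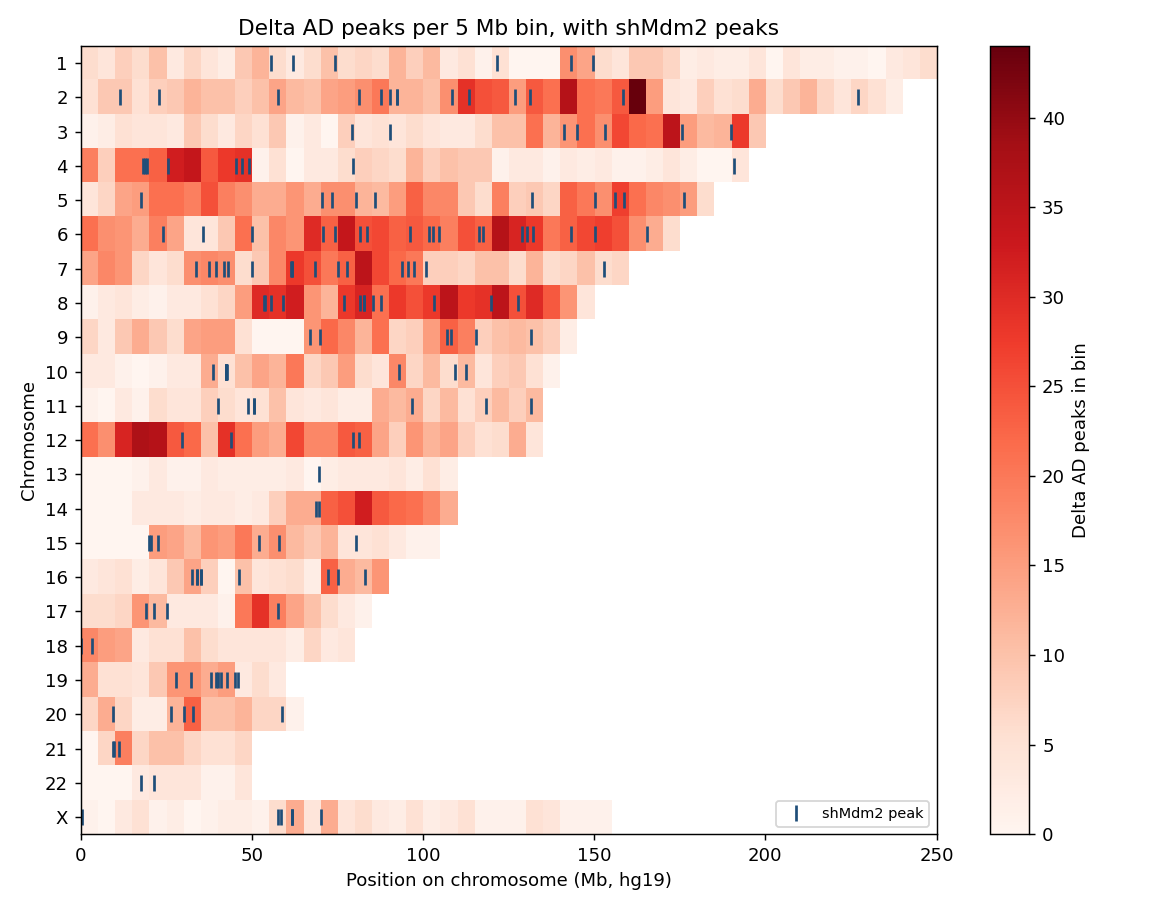
Delta AD peaks per 5 Mb bin along chromosomes 1 to 22 and X (x axis, hg19 position in Mb; colour, number of peaks from 0 to 44), with each shMdm2 peak as a vertical mark, from 1 library each. Dense blocks are visible on chromosome 8 beyond 45 Mb, on chromosome 3 beyond 120 Mb and on chromosome 2 between 105 and 170 Mb.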

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

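Among the settings, the common minimum at the lowest shMdm2 score, the top-ranked subset and the removal of chromosome Y and contigs from the shared peaks were added after the data were examined; the other settings had been fixed beforehand. Of 26 alternative values, 19 stayed close to the main value, within 1.5 times for counts and ratios, within the 95% interval for shares and within the quartiles for median scores. The other 7 all came from raising the score minimum. The 19 include the number of shMdm2 peaks at minimums of 38.45 and 50, which could not change because that list starts at 50. The minimums of 55 to 100 were not among the 26. At or above the Delta AD median of 38.45, 3871 Delta AD peaks were left and the ratio to shMdm2 was 20.7. At or above 50, 411 were left, the ratio was 2.20, and the share of Delta AD peaks was 6.57% on chromosome 6, 1.46% on unplaced contigs and 1.46% over 1 kb wide. Shared peaks numbered between 6 and 10 under the 6 alternatives tried. Random placement within 1 Mb gave 0.991 shared peaks on average. Promoter, annotation, gene list and motif results and their alternatives were not run, because they need an hg19 annotation or sequence. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group held 1 library. Depth is unknown, so a site listed in only 1 library may have fallen just under the other's score minimum: 2 of the 9 shared sites had Delta AD scores under 50, and 7 were left at that common minimum.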

Other observations

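All tests in this part were chosen after the peak lists had been seen. Chromosome Y carried 70 Delta AD peaks, 49 of them between 55 and 60 Mb, a region of repeated sequence by the known layout of this chromosome. Of the 70 peaks, 31 reached a score of 50, or 7.54% of all Delta AD peaks at that score (5.18 to 10.5), against 1.08% of the full list (0.843 to 1.36). No peak of either list lay on the mitochondrial genome.

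The longer Delta AD list is the first pattern. The lowest scores of the lists differ, 33.02 for Delta AD and 50 for shMdm2. A candidate explanation is that these different score minimums made the Delta AD list longer. For the 6067 Delta AD peaks below a score of 50 this stays open: leaving them out lowered the ratio 15.8-fold, from 34.6 to 2.20, but that fall is fixed by where the shMdm2 list ends, and how many shMdm2 peaks would lie below 50 cannot be read from it. At or above that score the ratio was 2.20 with a lower bound of 1.84. The different minimums do not account for this excess if equal scores mean equal enrichment, which need not hold. The bound also treats peaks as independent and may be too high. The variance of the Delta AD bin counts was 7.26 times their mean. The ratio was 2.72 (2.21 to 3.37, from 343 and 126 peaks) for scores from 50 to below 60 and 1.11 (0.777 to 1.60, from 68 and 61 peaks) at 60 or more, while at minimums of 70 to 100 it was between 1.45 and 2.25 with intervals that included equality. Library depth, the inputs, the amount of MDM2 and its form (the Delta AD variant) stay open and were not tested.

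The dense blocks are the second pattern. Neighbouring 5 Mb bins had alike counts (Spearman's rho across bins 0.770; at most 0.432 in 1000 shuffles of bins within chromosomes). A candidate explanation is extra DNA copies or another regional background of this cancer line, which would be present in both libraries. Of 166 shMdm2 peaks that were not shared, 51.2% (43.3 to 59.0) lay in the 25% of bins richest in Delta AD peaks, against a median of 30.7% in 10000 circular shifts along the chromosomes, none of which was as high, so the values that this explanation needs were there. The shifts did not leave out bins that can hold no peaks, which can lower their median. Gene density as the cause was not decided, since averages over whole chromosomes cannot test blocks within them. Across 23 chromosomes, peaks per Mb and protein-coding genes per Mb had a Spearman's rho of -0.0771 (bootstrap 95% interval -0.505 to 0.371, permutation p = 0.723). Pearson's r was -0.0764 (permutation p = 0.721), and r was -0.130 without chromosomes 17 and 19. The gene numbers were of GRCh38 and the lengths were hg19 ends of the last peaks. MDM2 left after knockdown and bound in the same blocks also stays open, since no input coverage was used.

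The group of 4 Delta AD peaks on chromosome 12 is the third pattern. A group of 4 or more Delta AD peaks within 40 kb was seen at 15 places on chromosomes 1 to 22 and X, and 2 peaks with scores of 80 or more within 40 kb were seen at this place and at 1 place on chromosome Y, with the limit of 80 set after the scores were seen. The 5 Mb on each side held 35 peaks, or 3.50 per Mb (exact Poisson 95% interval 2.44 to 4.87), against 3.64 per Mb on chromosome 12 as a whole, and none of the 35 scored above 48.19, against 87.44 and 103.5 in the group. Regional background at that place was not decided by the density, whose interval included that of the chromosome, and background limited to the group itself was not tested. MDM2 itself lies on the long arm of chromosome 12, and the cells overexpressed Mdm2 Delta AD. Reads of the introduced Mdm2 sequence may be one source of these 4 peaks, and binding of the protein at this place another. These cannot be told apart here, because placing the peak edges on exons needs an hg19 annotation and the sequence of the construct.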
